A study of Mus musculus with 18 samples.

How the data were processed

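Poly-A selected RNA was sequenced from mouse CD8+ T cells that were wild type (WT) or labelled cKO for GRP75, a conditional knockout. GRP75 is the mitochondrial chaperone encoded by Hspa9. Per the labels' protocols, naive CD8+ T cells came from lymph nodes and spleens of mice 8 weeks old, and effector and memory cells were grown from naive cells in culture. The 18 libraries form 6 groups, with 3 replicates of each genotype in each of the 3 subsets. Whether the replicates of a group were separate mice is not stated in the labels.

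Per the submitters' processing notes, the reads were handled with fastp, HISAT2 2.2.1, featureCounts 2.0.6 and DESeq2 1.42.0 on the mouse build GRCm39; the order, the settings, the annotation and the strand setting of the counting were not recorded. The authors deposited 1 table per subset, each with a signal value per gene and library, the mean of each group, and the log2 fold change of WT over cKO. A p-value and an adjusted p-value stand beside each fold change in the deposited tables. Within a library every deposited signal value was a whole multiple of the worth of 1 read, so the values are read counts divided by 1 size factor per library. Dividing by that worth gave whole reads for 100% of the values, with a largest deviation of 4.53e-06 reads against a tolerance of 1e-05. The recovered totals ranged from 14771251 to 18049774 reads per library. Size factors were set within each table, so levels of different subsets were compared on recovered reads only. Differences of the genotype effect used the deposited values, since each effect is taken within 1 table. The values are called normalised reads below, and means are given ± SD over the 3 replicates. Coordinates are those of the deposited tables.

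Before the data were examined, the tests, the gene lists, the rule for named genes and most alternative settings were fixed. The genotype effect (cKO minus WT) within each subset was tested with limma 3.58.1 (R 4.3.3) on log2(normalised reads + 1), with an intensity trend, for genes with at least 10 normalised reads in at least 3 libraries. This was the planned fallback for tables without counts, in place of the edgeR test planned for counts. The recovered reads would have allowed that edgeR test, which was run as an alternative. Fold changes are on that scale, and can differ from the ratio of the group means for genes with few reads. Differences of the genotype effect between subsets were tested as interaction terms in 1 limma model of all 18 libraries, on normalised reads of genes present in all 3 tables. For these differences the plan named edgeR on counts and gave no limma fallback. Without counts, the plan was to run no test of them. WT subsets were compared with edgeR 4.0.16, by its quasi-likelihood test with TMM normalization, on recovered reads given as CPM, the usual scaling to library totals. All gene tests were adjusted with the Benjamini-Hochberg method and called at an adjusted p under 0.05.

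A set of 36 gene lists, 912 genes in all, covered mitochondrial, stress, metabolic and T cell functions and markers of other cell types; 26 entries were matched through a synonym and 12 matched no gene. Lists were tested against the other genes with camera, from limma, on voom values of the recovered reads, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment. The same test with an estimated correlation, and fry, served as alternatives. Named genes were Hspa9, the 8 largest changes per direction (5 for interactions and WT comparisons) among called genes with a mean log2 CPM of at least 2, a symbol of a known gene and all 3 libraries of a group on 1 side of the other group, and up to 4 members with the smallest adjusted p of each list with at least 3 called genes or a called test. Single quantities per library were compared by an exact two-sided permutation test, which cannot give a p below 0.1 with 3 libraries against 3.

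The procedure was tested on simulated counts for the real genes. Of 50 genes changed by 1.5-fold, 37 were recovered in naive, 41 in effector and 37 in memory cells, and all 50 genes changed by 4-fold were recovered in each subset. Among unchanged genes, 9 of 13658, 9 of 13619 and 19 of 14348 were called in the same order. Of 50 interactions, 24, 23 and 24 were recovered at 1.5-fold for effector minus naive, memory minus naive and memory minus effector. For the WT comparisons 41, 42 and 42 of 50 were recovered at that size, for effector against naive, memory against naive and memory against effector. On simulated naive libraries, camera called all 3 moved lists and 0 of the others with the preset correlation. The simulated genes were drawn independently of each other, so false calls from correlation within a list could not appear there. For the gene tests, changed genes were drawn only from those with a mean of at least 50 reads. They made up a far smaller share of the genes than was called in the data. Recovery in the real comparisons may therefore differ.

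Alternatives covered the pseudocount, the filter, the scaling, edgeR, DESeq2 and voom on recovered reads, the fit of all 18 libraries, a replicate block, genes off the X and Y chromosomes, and leaving out each library in turn. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.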

Results

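The libraries hold poly-A RNA of mouse CD8+ T cells that were wild type (WT) or labelled cKO for GRP75, in 3 subsets: naive cells from lymph nodes and spleen, and effector and memory cells grown from naive cells in culture. Each genotype has 3 libraries in each subset, 18 libraries in all. Between 14771251 and 18049774 reads per library were assigned to genes of the mouse build GRCm39. The deposited tables list 23757 genes for naive, 24117 for effector and 24927 for memory cells. The common coefficient of variation between replicates, which edgeR calls biological, was 8.91% in naive, 5.50% in effector and 9.95% in memory cells. The labels do not state whether the replicates were separate mice. These values, and the SE and adjusted p-values below, may therefore not measure spread between mice. A rise or fall by a stated value is on the log2 scale throughout. Where a group held 0 reads of a gene, its fold is a lower bound against 3 reads over the group, which covers counting error only. In the WT comparisons these 3 reads were scaled to library totals and the other group by TMM, so the bounds are approximate.

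The labels name the deletion of Hspa9, the gene of GRP75, as the difference between the genotypes, so its own reads were compared first. Hspa9 (ENSMUSG00000024359, chromosome 18, 35070467 to 35087410) encodes a chaperone of the mitochondrial matrix. In naive cells, Hspa9 rose from 3992 ± 176 normalised reads in WT to 6438 ± 284 in the libraries labelled cKO (SD, n = 3), 1.61-fold, with a log2 fold change of 0.69 (SE 0.06, limma adjusted p = 1.3e-05). Memory cells held 4041 ± 119 Hspa9 reads in WT and 5637 ± 160.02 in cKO, a log2 fold change of 0.48 (SE 0.07, adjusted p = 3.4e-04). In effector cells the means were 2093 ± 79.7 in WT and 2339.9 ± 151 in cKO, a log2 fold change of 0.16 (SE 0.05, adjusted p = 0.033). In each subset all 3 cKO libraries lay above all 3 WT libraries, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The effect in effector cells differed from that in naive cells by -0.53 (SE 0.08, adjusted p = 7.4e-05), and the effect in memory cells exceeded that in effector cells by 0.32 (adjusted p = 0.017). Memory and naive cells differed by -0.21, which missed the threshold (adjusted p = 0.093). The deposited tables give the same direction, with log2 fold changes of WT over cKO of -0.69, -0.16 and -0.48 in naive, effector and memory cells.

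The call for Hspa9 in effector cells was lost without WT replicate 1 (adjusted p = 0.152), WT replicate 3 (0.0599), cKO replicate 2 (0.162) or cKO replicate 3 (0.119), and in a fit of all 18 libraries (0.0988). Reads summed over a gene do not show from which exons they come, the labels do not name the deleted part, and the small RNA gene Gm26109 lies inside Hspa9. These directions run against the label, so cKO below names the label of a library, and a rise or fall means libraries labelled cKO against libraries labelled WT.

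**Figure D1:**
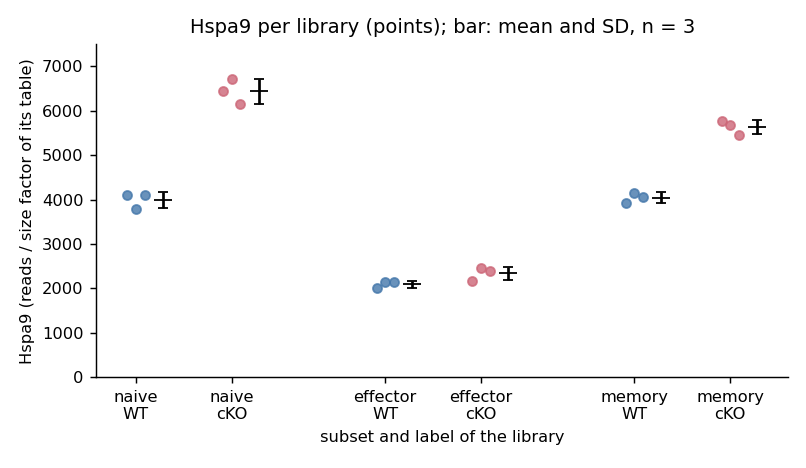
Normalised reads of Hspa9 (y axis, reads divided by the size factor of each table) per library (points, WT blue, cKO red) with mean and SD over 3 libraries, by subset and label. The cKO means of 6438, 2339.9 and 5637 in naive, effector and memory cells lie above the WT means of 3992, 2093 and 4041.

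The comparison in naive cells asks how the genotypes differ before activation in culture. In the naive libraries labelled cKO, targets of the stress transcription factor ATF4, cell cycle genes, inhibitory receptor genes and interferon-stimulated genes rose. Most mRNAs of the mitochondrial genome fell. Trib3, a pseudokinase induced by ATF4 and CHOP (ENSMUSG00000032715, chromosome 2, 152179342 to 152185952), rose from 13.0 ± 14.2 to 1299 ± 129.5 normalised reads (n = 3 per genotype, log2 fold change 7.04, SE 0.52, adjusted p = 2.9e-06). Soat2, an enzyme of cholesterol esterification, rose from 13.4 ± 4.50 to 953 ± 17.6 (log2 fold change 6.09, SE 0.20, adjusted p = 4.6e-09). Niban1, a stress-induced gene, rose from 109 ± 12.3 to 2262 ± 58.1 (log2 fold change 4.37, SE 0.10). Other large rises were those of Atf5, a transcription factor of the mitochondrial stress response (82.0 ± 15.0 to 1379 ± 106), and Bhlhe40, a transcription factor induced by T cell activation (41.1 ± 6.88 to 529 ± 45.1). The interferon-induced genes Oasl2 and Ifi44 rose by 4.19 (SE 0.20) and 3.56 (SE 0.15) on the log2 scale. Cpne4, a copine (ENSMUSG00000032564, chromosome 9, 104424485 to 104911743), fell from 409 ± 18.7 to 28.9 ± 6.54 (log2 fold change -3.80, SE 0.18, adjusted p = 5.8e-08). Hspa1b, a cytosolic heat shock chaperone, fell by 2.40 (SE 0.20) on the log2 scale, Grm6, a glutamate receptor, by 1.98 (SE 0.16) and Phf21b by 1.97 (SE 0.18).

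Of 13885 genes tested in naive cells, 3454 were called (limma, Benjamini-Hochberg adjusted p under 0.05), 1796 higher and 1658 lower in cKO, of which 712 and 180 changed at least 2-fold. The count was 2138 without naive cKO replicate 1 and 2127 without naive cKO replicate 2. TMM scaling moved naive genes by -0.12 on the log2 scale against scaling to library totals.

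Sex-linked transcripts differed between the naive genotypes. Xist, the RNA of the inactive X chromosome, fell from 16393 ± 1514 to 4428 ± 279 normalised reads (log2 fold change -1.89, SE 0.08, adjusted p = 2.6e-08). Ddx3y, a Y-linked RNA helicase, had 0 reads in the WT libraries and 2907 ± 143 normalised reads in cKO, at least 2766-fold higher. The Y-linked genes Eif2s3y, Kdm5d and Uty, chosen after their values were seen, also had 0 reads in WT and at least 1616-fold, 1212-fold and 463-fold more in cKO. No Y-linked gene of these 4 is listed in the effector or memory tables. Calls made up 24.2% of the genes tested on the X chromosome and 24.7% on autosomes (Fisher's exact test, two-sided p = 0.82). These shares cannot tell whether sex contributed to the naive calls, since sex may also change autosomal genes.

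**Figure D2:**
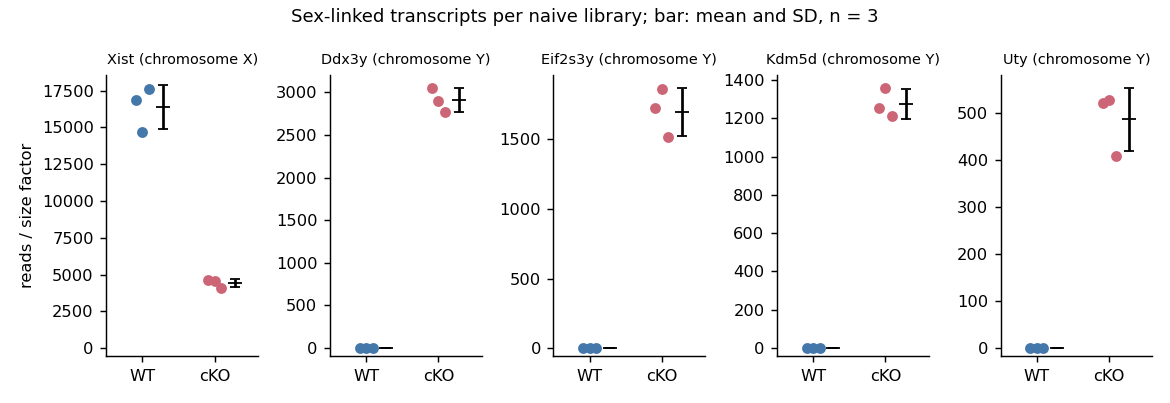
Normalised reads (y axis) of Xist and of 4 Y-linked genes per naive library (points, WT blue, cKO red) with mean and SD over 3 libraries, by label. Xist averages 16393 in WT and 4428 in cKO, and each Y-linked gene has 0 reads in WT, with Ddx3y at 2907 in cKO.

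Among 48 measured targets of ATF4 and the integrated stress response in naive cells, 40 rose, 1 fell and 7 did not pass (40 and 1 adjusted over the list alone), with a median log2 fold change of 1.34 (limma's camera, adjusted p = 3.8e-32). Members include Slc7a5, an amino acid transporter (816 ± 68.0 to 4048 ± 260.1), and Xpot, a tRNA exporter (log2 fold change 1.56, SE 0.06). Of the 13 mRNAs encoded by mitochondrial DNA, 12 fell and 1, mt-Nd3, rose by 0.71 (12 and 1 adjusted over the list alone), with a median of -1.67 (adjusted p = 1.9e-13, but adjusted p = 0.11 with an estimated correlation). The complex IV gene mt-Co1 fell from 171674 ± 14350.5 to 48345 ± 3869.8 and mt-Cytb by 1.67 (SE 0.09) on the log2 scale; nuclear copies of mitochondrial genes can share such reads. The share of reads from the mitochondrial chromosome was 2.12 ± 0.222% in WT and 0.821 ± 0.0756% in cKO. Nuclear genes of the respiratory chain and ATP synthase counted 0 rises and 22 falls among 77 (0 and 24 adjusted over the list alone, median -0.24, adjusted p = 5.8e-09, and adjusted p = 0.37 with an estimated correlation). Uqcrh of complex III fell by 0.78 (SE 0.10) and Cox7a2l, a factor of supercomplex assembly, by 0.68 (SE 0.06). In the cytosolic ribosome 57 of 78 genes fell and 2 rose (63 and 2 adjusted over the list alone, median -0.38, adjusted p = 2.0e-18, and adjusted p = 0.27 with an estimated correlation). Rpl14 of the large subunit fell by 0.52 (SE 0.07) and Rps4x of the small subunit by 0.48 (SE 0.07). The mitochondrial ribosome had 9 falls among 77 (5 adjusted over the list alone, adjusted p = 0.0081, and adjusted p = 0.25 with an estimated correlation). Mrpl28, of its large subunit, fell by 0.63 (SE 0.10). The tricarboxylic acid cycle had 5 falls among 23 (4 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.16 with an estimated correlation). Idh2, the mitochondrial isocitrate dehydrogenase, fell by 0.60 (SE 0.08). Mitochondrial chaperones and proteases other than Hspa9 were not called as a list (23 measured, 0 risen, 2 fallen, 0 and 1 adjusted over the list alone, median -0.07, adjusted p = 0.19).

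Cell cycle genes rose in naive cells, 28 of 35 with 0 falling (29 adjusted over the list alone, median 1.43, camera adjusted p = 1.6e-18). Mki67, the proliferation marker Ki-67, rose from 221 ± 23.2 to 1565 ± 128, Top2a, the DNA topoisomerase of dividing cells, by 2.31 (SE 0.10) on the log2 scale and Kif11, a spindle motor, by 2.57 (SE 0.12). Inhibitory receptor and exhaustion genes had 12 rises and 0 falls among 17 (14 adjusted over the list alone, median 0.98, adjusted p = 4.7e-08), including the orphan nuclear receptor Nr4a1 (1184 ± 101 to 4674 ± 197) and Rgs16 (2.39, SE 0.19). Of 38 interferon-stimulated genes 25 rose and 1 fell (25 and 2 adjusted over the list alone, median 0.50, adjusted p = 1.0e-13). The antiviral GTPase Mx1 rose by 1.63 (SE 0.07) and Rsad2 rose from 187 ± 16.5 to 860.4 ± 75.1. The lists of ATF4 targets, inhibitory receptors, cell cycle and interferon-stimulated genes were the 4 of 18 called in naive cells that held with an estimated correlation (adjusted p = 0.034, 0.034, 0.034 and 0.028). A replicate block ended these 4 calls (adjusted p = 0.20 for each). Immediate early genes counted 12 rises among 21 (12 and 1 fall adjusted over the list alone, adjusted p = 8.4e-09, and adjusted p = 0.25 with an estimated correlation). Fosb, an AP-1 subunit, rose from 119 ± 12.5 to 1258 ± 142. Of 21 p53 targets 15 rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 1.8e-07, and adjusted p = 0.071 with an estimated correlation). Plk2, a polo-like kinase, rose by 3.27 (SE 0.27). Apoptosis regulators had 11 rises among 22 (11 and 1 fall adjusted over the list alone, adjusted p = 8.8e-04, and adjusted p = 0.18 with an estimated correlation). The death-promoting Bcl2l11 rose by 0.98 (SE 0.06). Cytosolic heat shock genes had 8 falls and 0 rises among 17 (8 adjusted over the list alone, median -0.23, adjusted p = 0.0013, and adjusted p = 0.085 with an estimated correlation). Dnajb1, a co-chaperone of HSP70, fell by 0.51 (SE 0.07).

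T cell state genes of the naive libraries moved both ways. Among 23 effector genes 12 rose and 6 fell (13 and 7 adjusted over the list alone, median 0.89, adjusted p = 0.041, and adjusted p = 0.18 with an estimated correlation). The chemokine gene Ccl5 rose from 59.4 ± 3.62 to 444 ± 15.0 and Irf4 by 2.08 (SE 0.10) on the log2 scale, while Prf1, which encodes perforin, fell by 1.37 (SE 0.08). Naive and central memory genes were not called as a list (21 measured, 4 risen, 10 fallen, the same adjusted over the list alone, adjusted p = 0.13). The survival gene Bcl2 rose from 4529 ± 163 to 8958 ± 545 and Il7r, the IL-7 receptor, fell by 0.48 (SE 0.06). CD8 T cell identity genes fell, 9 of 14 (13 adjusted over the list alone, median -0.23, adjusted p = 5.4e-07, and adjusted p = 0.082 with an estimated correlation). Cd8b1, the CD8 beta chain, fell by 0.46 (SE 0.06) and Thy1 by 0.48 (SE 0.07). Markers of gamma-delta T cells rose, 5 of 6 (5 adjusted over the list alone, median 3.53, adjusted p = 1.9e-05, and adjusted p = 0.071 with an estimated correlation). Trgc2, a T cell receptor gamma constant gene with close paralogs, rose from 12.8 ± 6.55 to 214 ± 24.4. Of 13 B cell markers 9 rose and 2 fell (10 and 3 adjusted over the list alone, median 1.79, adjusted p = 0.0038, and adjusted p = 0.11 with an estimated correlation). Cd74 rose by 1.79 (SE 0.14) and Ighm, the IgM heavy chain, fell by 0.47 (SE 0.07). Summed over the list, gamma-delta markers went from 10.9 ± 1.01 to 61.6 ± 4.75 CPM, B cell markers from 467 ± 22.0 to 407 ± 20.3 and CD4 T cell markers from 57.0 ± 4.00 to 84.7 ± 1.82. WT naive libraries held at least 10 normalised reads of 4 of the 6 gamma-delta, 10 of the 13 B cell and 7 of the 8 CD4 markers measured, and 0 marker genes are in another list.

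**Figure D3:**
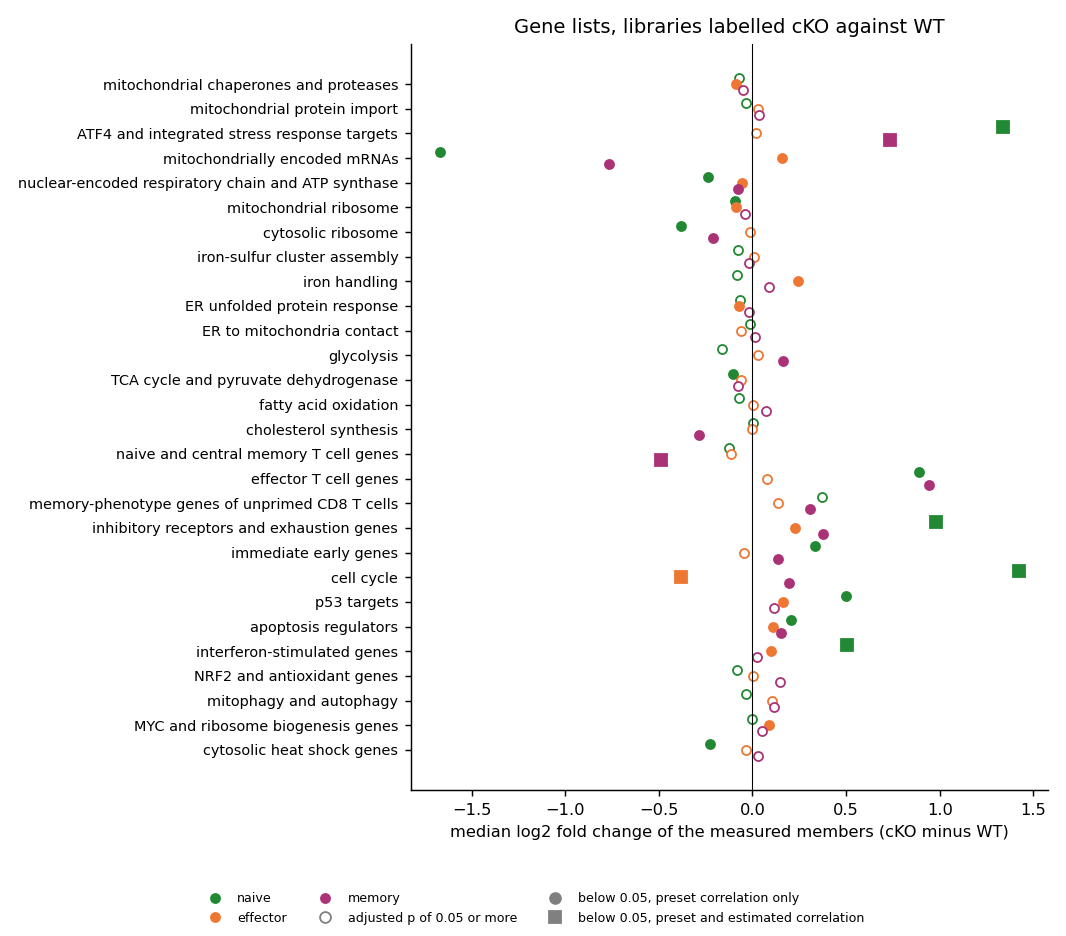
Median log2 fold change (cKO minus WT, x axis) over the measured members of each gene list (y axis) in naive (green), effector (orange) and memory (purple) cells; open circles have a camera adjusted p of 0.05 or more, filled circles lie below 0.05 with the preset correlation, and squares with the estimated correlation as well. The ATF4 list lies at 1.34 in naive, 0.02 in effector and 0.73 in memory cells, and mitochondrially encoded mRNAs lie at -1.67, 0.16 and -0.77.

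The comparison in effector cells asks how the genotypes differ after activation and expansion in culture. Cell cycle genes fell in the effector libraries labelled cKO, and marker lists of 5 other cell types rose. Klra1 and Klra6, genes of Ly49 receptors of NK and T cells that share reads with close paralogs, rose from 43.2 ± 11.5 to 686 ± 86.3 and from 81.3 ± 8.73 to 1201 ± 78.7 normalised reads (n = 3 per genotype, log2 fold changes 3.99, SE 0.17, and 3.87, SE 0.10). Their paralogs Klra7 and Klra10 rose by 3.48 (SE 0.08) and 3.29 (SE 0.16) on the log2 scale. Hba-a1, an alpha-globin gene with a close paralog, rose from 50.4 ± 2.61 to 471 ± 21.0 (log2 fold change 3.20, SE 0.12, adjusted p = 8.6e-13). Gpr55, a G protein-coupled receptor (ENSMUSG00000049608, chromosome 1, 85866039 to 85888729), fell from 334 ± 6.13 to 45.7 ± 6.39 (log2 fold change -2.85, SE 0.14, adjusted p = 4.7e-11). Nrp1, neuropilin, fell from 414 ± 13.4 to 123 ± 9.03. Smyd1, which lies next to Cd8b1, fell by 1.56 (SE 0.10) and Itgad, integrin alpha D, by 1.23 (SE 0.15).

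Of 13815 genes tested in effector cells, 2779 were called (limma), 1485 higher and 1294 lower in cKO, of which 388 and 103 changed at least 2-fold. The fit of all 18 libraries called 1519.

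In effector cells 34 of 35 cell cycle genes fell (34 adjusted over the list alone, median -0.38, camera adjusted p = 1.7e-29, and adjusted p = 0.018 with an estimated correlation). Mki67 fell from 20542 ± 893 to 14542 ± 359.8, Top2a by 0.46 (SE 0.03) on the log2 scale, and Cenpe, a kinetochore motor, by 0.50 (SE 0.04). ATF4 targets were not called as a list (42 measured, 7 risen, 3 fallen, 8 and 3 adjusted over the list alone, median 0.02, adjusted p = 0.31). Ddit4, an inhibitor of mTORC1, rose by 0.53 (SE 0.06), Stc2 rose by 1.31 (SE 0.19) and Niban1 fell by 0.28 (SE 0.04). Of 13 mitochondrially encoded mRNAs 5 rose (6 adjusted over the list alone, median 0.16, adjusted p = 3.1e-04, and adjusted p = 0.35 with an estimated correlation). The mRNA mt-Cytb rose from 35464 ± 902 to 44778 ± 1257. Reads from the mitochondrial chromosome made up 1.86 ± 0.0603% in WT and 2.17 ± 0.0488% in cKO. Mitochondrial chaperones and proteases had 2 falls among 23 (1 adjusted over the list alone, adjusted p = 0.020, and adjusted p = 0.17 with an estimated correlation). Hspd1, the chaperonin of the mitochondrial matrix, fell by 0.21 (SE 0.04). Iron handling genes had 9 rises among 15 (10 adjusted over the list alone, median 0.24, adjusted p = 8.0e-04, and adjusted p = 0.11 with an estimated correlation). The iron exporter Slc40a1 rose by 1.55 (SE 0.21) and the mitochondrial iron importer Slc25a37 by 0.44 (SE 0.06). Erythroid and myeloid cells are known to express these genes too, and in the same libraries summed erythroid markers rose 5.55-fold and myeloid markers 1.53-fold. Among 25 genes of the unfolded protein response of the endoplasmic reticulum 7 fell and 4 rose (the same adjusted over the list alone, adjusted p = 0.043, and adjusted p = 0.24 with an estimated correlation). The chaperone Hsp90b1 fell by 0.31 and the sensor Ern1 rose by 0.43. Inhibitory receptor genes had 9 rises and 4 falls among 19 (9 and 4 adjusted over the list alone, median 0.23, adjusted p = 0.0098, and adjusted p = 0.12 with an estimated correlation). Entpd1, the ectonucleotidase CD39, rose by 0.71 (SE 0.06) and Tigit by 0.50 (SE 0.05).

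Apoptosis regulators of effector cells had 6 rises and 1 fall among 23 (6 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.013, and adjusted p = 0.12 with an estimated correlation). Bcl2 rose from 699.5 ± 25.3 to 2207 ± 45.2 and Bcl2l11 by 0.56 (SE 0.05) on the log2 scale. Of 22 p53 targets 8 rose (9 adjusted over the list alone, adjusted p = 0.0010, and adjusted p = 0.088 with an estimated correlation). Pmaip1, the death-promoting Noxa, rose by 0.33 (SE 0.04). The lists of naive genes (adjusted p = 0.97; median -0.11, mean 0.00) and effector genes (adjusted p = 0.24) were not called. Within them, Slamf6 fell by 0.82 (SE 0.06), Klrk1, the receptor NKG2D, rose by 0.63 (SE 0.04) and Irf4 fell by 0.48 (SE 0.05). CD8 T cell identity genes were not called (adjusted p = 0.18), although Cd8b1 fell from 20714 ± 325 to 12705 ± 235. Itgb1, an integrin of the memory-phenotype list, which was not called (adjusted p = 0.53), fell from 22082 ± 641 to 12501 ± 536.

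Markers of 5 other cell types rose in effector cells, and these 5 lists and the cell cycle list were the 6 of 17 called lists that held with an estimated correlation. A replicate block ended these 6 calls (adjusted p = 0.17 for each). All 7 erythroid markers rose (7 adjusted over the list alone, median 2.56, adjusted p = 1.3e-11, and adjusted p = 0.025 with an estimated correlation), as did 15 of 19 myeloid markers with 1 fall (17 and 1 adjusted over the list alone, adjusted p = 1.1e-11, and adjusted p = 0.046 with an estimated correlation). NK markers had 8 rises and 1 fall among 9 (8 and 1 adjusted over the list alone), gamma-delta markers 6 rises among 7 (6 adjusted over the list alone) and B cell markers 8 rises among 17 (9 adjusted over the list alone), each with an adjusted p of 0.025 with an estimated correlation. Klre1, an NK receptor gene, rose from 1599.9 ± 148 to 4723 ± 103, Mpeg1, a macrophage pore protein, by 2.18 (SE 0.09) on the log2 scale, and Cd74, the invariant chain of class II molecules, from 1197 ± 20.9 to 2869 ± 126. Summed over each list, NK markers went from 189.8 ± 6.51 to 449 ± 6.36 CPM, erythroid markers from 21.0 ± 0.898 to 117 ± 2.45 and gamma-delta markers from 26.1 ± 1.87 to 107 ± 2.69. The WT effector libraries held at least 10 normalised reads of all 9 NK, 17 of 17 B cell, 16 of 19 myeloid, 6 of 7 erythroid and 5 of 7 gamma-delta markers.

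**Figure D4:**
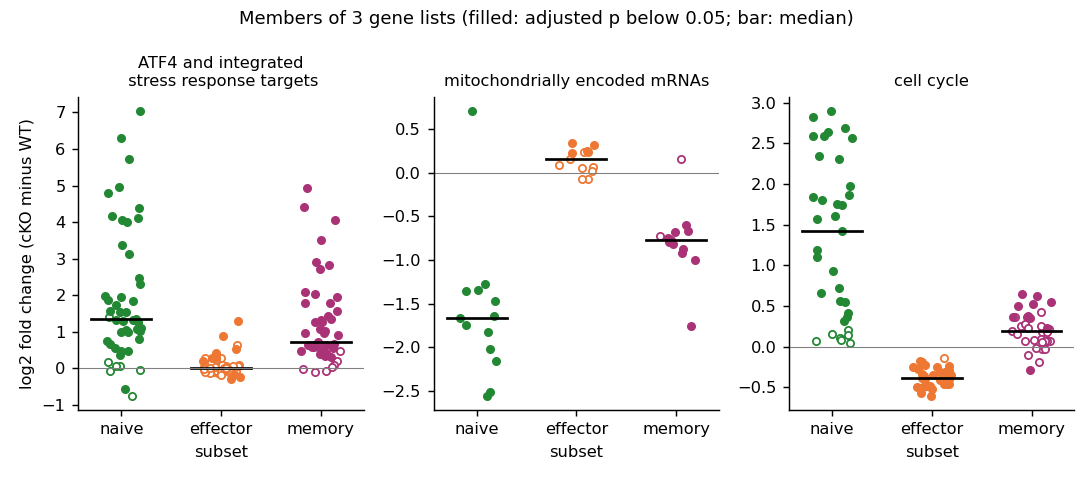
Log2 fold change (cKO minus WT, y axis) of each measured member (points, filled where the limma adjusted p is under 0.05) of 3 gene lists in each subset (x axis), with a bar at the median. The cell cycle medians are 1.43 in naive, -0.38 in effector and 0.19 in memory cells.

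The comparison in memory cells asks how the genotypes differ in cells cultured to a memory state. ATF4 targets rose and genes of naive and central memory T cells fell in the memory libraries labelled cKO. Myeloid, NK and gamma-delta marker lists were called higher with the preset correlation only (adjusted p = 0.099, 0.13 and 0.099 with an estimated correlation). Cox6a2, a complex IV subunit isoform of heart and muscle, rose from 11.3 ± 3.45 to 544 ± 93.3 normalised reads (n = 3 per genotype, log2 fold change 5.50, SE 0.22, adjusted p = 1.7e-08). Siglech, a receptor of plasmacytoid dendritic cells (ENSMUSG00000051504, chromosome 7, 55417926 to 55428673), rose from 16.5 ± 4.59 to 649 ± 52.9 (log2 fold change 5.25, SE 0.21, adjusted p = 1.5e-08). Chil3, which encodes the macrophage protein Ym1, Ltf, which encodes lactoferrin, and Ngp, of neutrophil granules, rose by 5.08 (SE 0.27), 4.35 (SE 0.15) and 4.22 (SE 0.16) on the log2 scale. Lyz2, lysozyme of myeloid cells, rose from 114 ± 15.0 to 2249 ± 354, and Trib3 from 29.7 ± 7.65 to 641 ± 63.5. Slc28a2b, of the nucleoside transporter family (chromosome 2, 122315422 to 122358521), fell from 3597 ± 173 to 521 ± 15.4 (log2 fold change -2.78, SE 0.07, adjusted p = 1.1e-09). Dapl1, a gene of naive and central memory T cells, fell from 1599 ± 101 to 304 ± 59.3 and the amino acid transporter Slc6a19 by 2.32 (SE 0.10) on the log2 scale. Other falls were those of the lipocalin Lcn4 (-1.61, SE 0.10), the carboxypeptidase Cpm (-1.58, SE 0.10) and the potassium channel Kcna2 (-1.50, SE 0.14).

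Of 14622 genes tested in memory cells, 2793 were called (limma), 1769 higher and 1024 lower in cKO, of which 922 and 157 changed at least 2-fold. The count was 1830 without memory WT replicate 3 (1343 higher and 487 lower) and 1836 without memory cKO replicate 3 (1151 higher and 685 lower).

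In memory cells 40 of 47 ATF4 targets rose and 0 fell (42 and 0 adjusted over the list alone, median 0.73, camera adjusted p = 3.7e-27, and adjusted p = 0.028 with an estimated correlation). Atf5 rose from 94.1 ± 2.86 to 713 ± 93.3, the stress transcription factor Atf3 by 2.73 (SE 0.13) and Niban1 by 1.79 (SE 0.09). Naive and central memory genes had 17 falls, 1 rise and 3 not passing among 21 (18 and 1 adjusted over the list alone, median -0.49, adjusted p = 1.5e-11, and adjusted p = 0.028 with an estimated correlation). Il6ra, the IL-6 receptor, fell from 3163 ± 61.9 to 1463 ± 165 and Tcf7, the transcription factor TCF-1, from 29523 ± 957 to 19192 ± 503, whereas Bcl2 rose from 3701 ± 169.9 to 7079 ± 151. Those 2 lists were the ones of 19 called that held with an estimated correlation, and a replicate block ended both calls (adjusted p = 0.24 for each). Of 13 mitochondrially encoded mRNAs 11 fell (12 adjusted over the list alone, median -0.77, adjusted p = 4.9e-07, and adjusted p = 0.29 with an estimated correlation). The mRNA mt-Co1 went from 187748 ± 8776 to 106978 ± 14817 and mt-Cytb fell by 0.77 (SE 0.13). The mitochondrial share of reads was 2.41 ± 0.0679% in WT and 1.55 ± 0.268% in cKO. Cholesterol synthesis genes had 9 falls among 23 (14 adjusted over the list alone, median -0.29, adjusted p = 1.6e-06, and adjusted p = 0.099 with an estimated correlation). Insig1, a sterol sensor, fell by 0.65 (SE 0.07). Cytosolic ribosome genes had 4 falls among 78 (1 adjusted over the list alone, median -0.21, adjusted p = 3.2e-07, and adjusted p = 0.64 with an estimated correlation). Rpl30 fell from 7385 ± 692 to 3299 ± 1072.

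Effector T cell genes of memory cells had 20 rises and 3 falls among 28 (22 and 3 adjusted over the list alone, median 0.94, adjusted p = 2.8e-13, and adjusted p = 0.099 with an estimated correlation). Fasl, a death ligand, rose from 153 ± 10.1 to 839 ± 29.2, the chemokine gene Xcl1 by 2.29 (SE 0.11) and Klrk1 by 1.74 (SE 0.07) on the log2 scale. Among 15 memory-phenotype genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 1.5e-05, and adjusted p = 0.099 with an estimated correlation). Il2rb, the shared receptor chain for IL-2 and IL-15, rose from 7778 ± 69.4 to 17851 ± 335 and Cd44 by 0.80 (SE 0.07). Inhibitory receptor genes had 11 rises and 2 falls among 18 (12 and 2 adjusted over the list alone, adjusted p = 3.2e-05, and adjusted p = 0.099 with an estimated correlation). Bhlhe40 rose by 1.86 (SE 0.07), Cd160 rose by 1.53 (SE 0.09) and Ctla4 fell by 1.16 (SE 0.08). NK cells are known to express Klrk1, Fasl, Xcl1 and Cd160 too, and NK markers summed to 25.0 ± 2.51 CPM in WT and 147 ± 9.97 in cKO. Cell cycle genes had 10 rises and 1 fall among 35 (11 and 1 adjusted over the list alone, median 0.19, adjusted p = 0.0017, and adjusted p = 0.17 with an estimated correlation). Mki67 rose by 0.50 (SE 0.09) and the mitotic transcription factor Foxm1 by 0.65 (SE 0.10). Apoptosis regulators had 7 rises among 22 (7 adjusted over the list alone, adjusted p = 0.0025, and adjusted p = 0.099 with an estimated correlation). Bcl2l1, the survival protein Bcl-xL, rose by 0.97 (SE 0.12). Of 14 CD8 T cell identity genes 4 fell and 1 rose (6 and 1 adjusted over the list alone, adjusted p = 0.0014, and adjusted p = 0.58 with an estimated correlation). Cd8b1 fell from 15263 ± 970.4 to 8570.4 ± 791. Interferon-stimulated genes were not called (median 0.03, adjusted p = 0.81).

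Myeloid markers had 17 rises among 19 in memory cells (19 adjusted over the list alone, median 3.00, adjusted p = 1.6e-19, and adjusted p = 0.099 with an estimated correlation), including Mpeg1 (271 ± 10.3 to 3074 ± 214). NK markers had 7 rises among 9 (7 adjusted over the list alone, adjusted p = 5.9e-06, and adjusted p = 0.13 with an estimated correlation). Klre1 rose by 2.96 (SE 0.09). Gamma-delta markers had 6 rises among 7 (6 adjusted over the list alone, adjusted p = 2.6e-07, and adjusted p = 0.099 with an estimated correlation). Trgc2 rose by 3.77 (SE 0.16). B cell markers had 14 rises among 17 (16 adjusted over the list alone, adjusted p = 1.9e-13, and adjusted p = 0.15 with an estimated correlation). The class II gene H2-Ab1 rose from 942 ± 77.5 to 4887 ± 454. Summed over each list, myeloid markers went from 98.0 ± 8.81 to 757 ± 88.3 CPM (7.72-fold), B cell markers from 1122 ± 69.5 to 2687 ± 264 (2.40-fold) and gamma-delta markers from 56.9 ± 2.26 to 188 ± 18.3 (3.31-fold). The WT memory libraries held at least 10 normalised reads of 17 of 19 myeloid, 8 of 9 NK, 17 of 17 B cell and 7 of 7 gamma-delta markers.

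**Figure D5:**
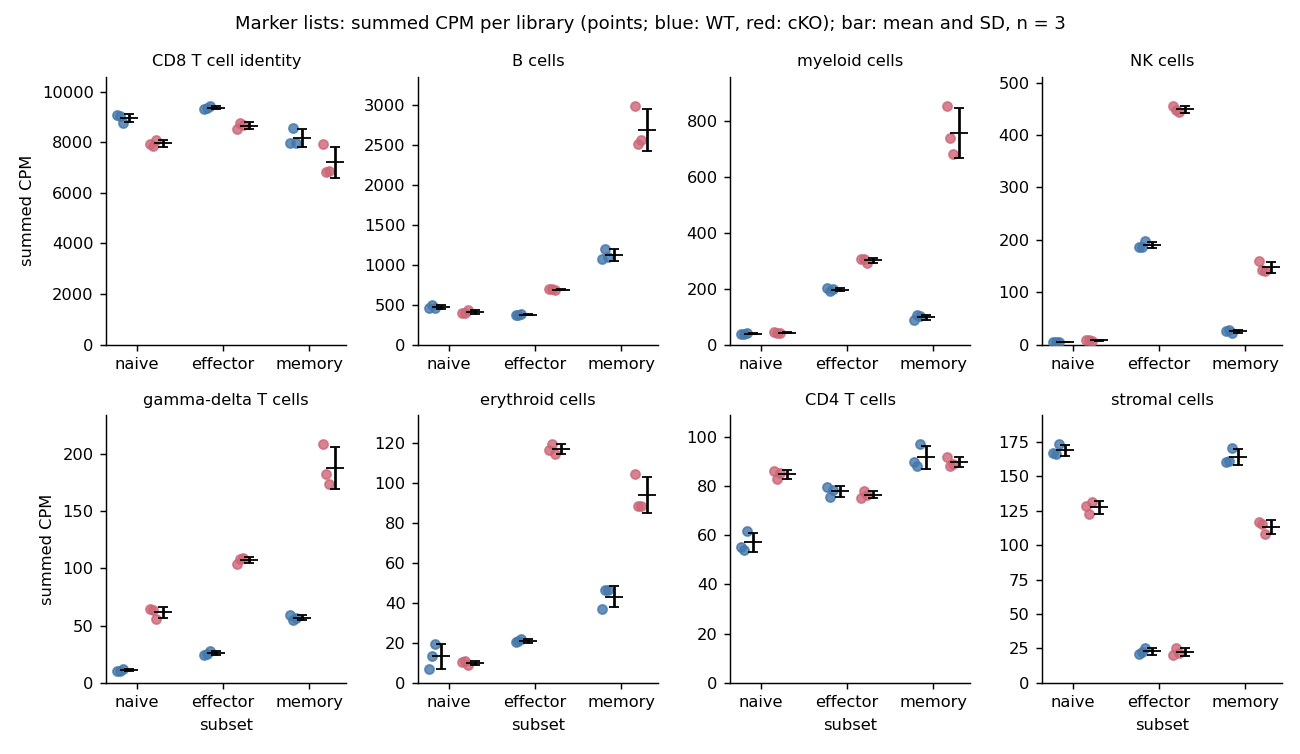
Summed CPM (y axis, linear, from 0) of 8 marker lists per library (points, WT blue, cKO red) with mean and SD over 3 libraries, by subset (x axis). Myeloid markers in memory cells average 98.0 in WT and 757 in cKO, and CD8 T cell identity genes lie within 0.882 to 0.924 of the WT mean in cKO in each subset.

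Whether the genotype effect differs between subsets was tested as an interaction. The rise of ATF4 targets and cell cycle genes in naive cells was larger than in either cultured subset, and naive and central memory genes fell more in memory cells than in the other subsets. Only the naive cKO libraries held reads of Ddx3y, Eif2s3y, Kdm5d and Uty. Differences from naive cells therefore cannot be told apart from this sex difference between the naive groups. Trib3, Soat2, Niban1 and Fosb had genotype effects in effector cells that differed from those in naive cells by -6.39 (SE 0.59, adjusted p = 3.5e-08), -5.86 (SE 0.21), -4.65 (SE 0.12) and -4.40 (SE 0.13) on the log2 scale. App, the amyloid precursor gene, and Pak1, a kinase, had effects higher in effector cells by 2.97 (SE 0.25) and 2.55 (SE 0.26), and mt-Co2 by 2.67 (SE 0.45). Of 15694 genes, 2902 differed between effector and naive cells (1382 higher and 1520 lower in effector cells). ATF4 targets differed by a median of -1.29 (2 higher and 40 lower of 49, 2 and 41 adjusted over the list alone, camera adjusted p = 1.3e-35) and cell cycle genes by -1.68 (33 of 35 lower, 34 adjusted over the list alone), Mki67 by -3.32 (SE 0.11). Mitochondrially encoded mRNAs differed by 1.81 (12 of 13 higher, 12 and 1 lower adjusted over the list alone), mt-Co1 by 2.08 (SE 0.14). Inhibitory receptor genes differed by -0.83 (1 higher and 10 lower of 19, 1 and 11 adjusted over the list alone) and p53 targets by -0.46 (1 higher and 8 lower of 22, 1 and 12 adjusted over the list alone). Those 5 of 12 called lists held with an estimated correlation (adjusted p = 6.4e-05, 2.9e-05, 0.039, 0.0011 and 0.018 in the order given).

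Between memory and naive cells the genotype effect differed for 2652 genes, 1239 higher and 1413 lower in memory cells. The largest differences by the naming rule included Naaa, a lysosomal amidase (3.04, SE 0.18), Hspa1b (2.70, SE 0.23), Oasl2 (-3.90, SE 0.46) and Fosb (-3.52, SE 0.13). ATF4 targets differed by a median of -0.50 (3 higher and 28 lower of 49, 3 and 31 adjusted over the list alone), with Niban1 at -2.59 (SE 0.12), and cell cycle genes by -1.38 (25 of 35 lower, 27 adjusted over the list alone), with Top2a at -1.93 (SE 0.10). Naive and central memory genes differed by -0.34 (12 of 21 lower, 14 adjusted over the list alone), Ccr7, a lymph node homing receptor, by -1.12 (SE 0.11). Interferon-stimulated genes differed by -0.50 (1 higher and 21 lower of 38, 1 and 26 adjusted over the list alone), Mx1 by -1.21 (SE 0.09). Inhibitory receptor genes differed by -0.55 (3 higher and 8 lower of 19, the same adjusted over the list alone), Ctla4 by -1.84 (SE 0.11), and p53 targets by -0.37 (10 of 22 lower, 11 adjusted over the list alone). These 6 of 18 called lists held with an estimated correlation (adjusted p = 0.0044, 7.5e-04, 4.2e-04, 0.022, 0.015 and 0.0044 in the order given).

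Between memory and effector cells 1367 genes differed, 745 higher and 622 lower in memory cells. Trib3 differed by 3.76 (SE 0.59), the NK receptor gene Klrb1c by 3.48 (SE 0.32) and Soat2 by 2.93 (SE 0.21), against -2.18 (SE 0.27) for Igf1r, the IGF-1 receptor. ATF4 targets differed by 0.74 (33 of 49 higher, 36 adjusted over the list alone, camera adjusted p = 2.6e-29), effector genes by 0.81 (15 higher and 1 lower of 29, 19 and 1 adjusted over the list alone) and memory-phenotype genes by 0.61 (7 of 15 higher, 8 adjusted over the list alone). Cell cycle genes differed by 0.57 (18 of 35 higher, 29 adjusted over the list alone), inhibitory receptor genes by 0.58 (6 higher and 2 lower of 19, 10 and 2 adjusted over the list alone) and myeloid markers by 1.36 (9 of 18 higher, 10 adjusted over the list alone). Naive and central memory genes differed by -0.47 (13 of 21 lower, 14 adjusted over the list alone), Il7r by -1.05 (SE 0.07), and cholesterol synthesis genes by -0.32 (3 of 23 lower, 6 adjusted over the list alone), Insig1 by -0.88 (SE 0.10). These 8 of 17 called lists held with an estimated correlation (adjusted p = 1.0e-04, 0.0013, 0.0012, 1.0e-04, 0.0032, 0.011, 7.4e-05 and 0.010 in the order given). Mitochondrially encoded mRNAs differed by -0.98 (7 of 13 lower, 11 adjusted over the list alone, adjusted p = 4.1e-11, and adjusted p = 0.057 with an estimated correlation). NK markers, called higher (adjusted p = 0.042, and adjusted p = 0.12 with an estimated correlation), had a median of -0.02 and a mean of 0.58.

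The WT libraries alone were compared to show how the subsets differ without a genotype effect. WT effector cells held more transcripts of cell cycle and effector genes than WT naive cells and fewer of naive and central memory genes. Esm1, which encodes endocan, had 0 reads in naive cells and 207 ± 9.85 CPM in effector cells (n = 3 per subset), at least 3318-fold higher. Lgals3, which encodes galectin-3, was at least 2492-fold higher. Gzma, granzyme A, rose from 0.982 ± 0.554 to 4693 ± 186 CPM (log2 fold change 12.23, SE 0.18, edgeR adjusted p = 5.6e-26). Ramp1, a receptor-modifying protein, fell from 74.3 ± 2.27 to 0.471 ± 0.148 CPM (log2 fold change -7.29, SE 0.21, adjusted p = 2.0e-20) and Kcna2 by 6.62 (SE 0.18). Of 15659 genes, 10484 differed, 5306 higher and 5178 lower in effector cells. Each of the 35 cell cycle genes rose (35 adjusted over the list alone, median 4.58, camera adjusted p = 2.1e-24), Mki67 by 6.70 (SE 0.10), and of 29 effector genes 28 rose and 1 fell (28 and 1 adjusted over the list alone, median 5.09). Naive and central memory genes had 19 falls and 1 rise among 21 (19 and 1 adjusted over the list alone, median -2.83). Tcf7 fell by 3.75 (SE 0.07). Interferon-stimulated genes had 33 falls and 3 rises among 38 (34 and 3 adjusted over the list alone, median -0.99). Oas2, an antiviral enzyme, fell by 5.51 (SE 0.12). Those 4 were among 10 of 21 called lists that held with an estimated correlation (adjusted p = 2.1e-04, 0.0048, 4.5e-05 and 0.029 in the order given). Cytosolic ribosome genes had 69 falls and 2 rises among 78 (71 and 2 adjusted over the list alone, median -0.93, adjusted p = 3.2e-15, and adjusted p = 0.28 with an estimated correlation).

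WT memory cells held more transcripts of immediate early and effector genes and of B cell markers than WT naive cells. Fcmr, an Fc receptor for IgM, had 0 reads in naive cells and 10.2 ± 0.692 CPM in memory cells, at least 164-fold higher, and Lgals3 was at least 83.6-fold higher. Klrc1, the NK receptor NKG2A with close paralogs, rose from 0.0841 ± 0.0728 to 40.9 ± 2.26 CPM (log2 fold change 8.83, SE 0.23, edgeR adjusted p = 3.4e-20). Wls, a Wnt secretion factor, fell from 299 ± 17.9 to 33.3 ± 1.16 CPM (log2 fold change -3.17, SE 0.08) and Ddit4 by 2.31 (SE 0.11). Of 15659 genes, 5804 differed, 3121 higher and 2683 lower in memory cells. Immediate early genes had 18 rises and 2 falls among 21 (18 and 2 adjusted over the list alone, median 1.85, camera adjusted p = 1.6e-21). Fosb rose by 6.87 (SE 0.11). Effector genes had 25 rises and 1 fall among 29 (25 and 1 adjusted over the list alone, median 2.85). Ccl5 rose by 5.98 (SE 0.13). Memory-phenotype genes had 14 rises among 15 (14 adjusted over the list alone, median 2.04), and Cd44, an adhesion receptor of activated T cells, rose by 2.82 (SE 0.08). B cell markers had 16 rises among 17 (16 adjusted over the list alone, median 5.03). Cd74 went from 5.24 ± 0.518 to 172 ± 17.5 CPM. Those 4 were among 10 of 17 called lists that held with an estimated correlation (adjusted p = 0.0082, 0.0042, 9.6e-05 and 0.011 in the order given).

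WT memory cells differed from WT effector cells in 9590 genes, 4801 higher and 4789 lower in memory cells. Ccr7 rose from 27.3 ± 0.598 CPM in effector cells to 1421 ± 90.3 in memory cells (log2 fold change 5.70, SE 0.10, edgeR adjusted p = 8.9e-24), and Slc28a2b from 3.68 ± 0.496 to 219 ± 9.35. Klrg1, a receptor of terminal effector cells, fell from 540.1 ± 14.6 to 1.54 ± 0.137 CPM (log2 fold change -8.45, SE 0.13), against log2 fold changes of -7.65 (SE 0.12) for the chemokine receptor gene Cx3cr1 and -7.58 (SE 0.13) for Gzma. All 21 naive and central memory genes rose (21 adjusted over the list alone, median 2.95, camera adjusted p = 5.1e-20). Tcf7 rose by 3.99 (SE 0.07). Each of the 35 cell cycle genes fell (35 adjusted over the list alone, median -2.77), and effector genes had 24 falls and 2 rises among 29 (24 and 2 adjusted over the list alone, median -3.28). MYC and ribosome biogenesis genes had 23 rises among 25 (23 adjusted over the list alone, median 0.91). The transcription factor gene Myc rose by 2.13 (SE 0.10). Those 4 were among 6 of 15 called lists that held with an estimated correlation (adjusted p = 8.5e-06, 8.3e-05, 0.0043 and 0.0095 in the order given). Cytosolic ribosome genes had 74 rises and 1 fall among 78 (75 and 2 adjusted over the list alone, adjusted p = 4.7e-18, and adjusted p = 0.31 with an estimated correlation).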

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

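The tests of explanations below were chosen only after the results were seen, whereas the tests of differences between subsets and the counts over other splits were planned. The plan named edgeR on counts for those differences, and limma on normalised reads was run in its place.

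The results listed here were picked out because a test of the difference between 2 subsets called the genotype effect unequal, with an estimated correlation for gene lists. For effector minus naive cells, median differences of log2 fold change were -1.29 for targets of ATF4 (adjusted p = 6.4e-05), -1.68 for cell cycle genes (adjusted p = 2.9e-05) and -0.83 for inhibitory receptors (adjusted p = 0.0011). They were -0.46 for p53 targets (adjusted p = 0.018) and 1.81 for mitochondrially encoded mRNAs (adjusted p = 0.039), and Hspa9 differed by -0.53 (adjusted p = 7.4e-05). For memory minus naive cells, the medians were -0.50 for targets of ATF4 (adjusted p = 0.0044), -0.34 for naive and central memory genes (adjusted p = 4.2e-04) and -0.55 for inhibitory receptors (adjusted p = 0.015). Cell cycle genes differed by -1.38 (adjusted p = 7.5e-04), p53 targets by -0.37 (adjusted p = 0.0044) and interferon-stimulated genes by -0.50 (adjusted p = 0.022).

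For memory minus effector cells, the medians were 0.74 for targets of ATF4 (adjusted p = 1.0e-04), 0.57 for cell cycle genes (adjusted p = 1.0e-04), -0.32 for cholesterol synthesis (adjusted p = 0.010) and -0.47 for naive and central memory genes (adjusted p = 7.4e-05). Effector genes differed by 0.81 (adjusted p = 0.0013), memory-phenotype genes by 0.61 (adjusted p = 0.0012), inhibitory receptors by 0.58 (adjusted p = 0.0032) and myeloid markers by 1.36 (adjusted p = 0.011). Hspa9 differed by 0.32 (adjusted p = 0.017).

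Y-linked transcripts and lower Xist set the naive cKO libraries apart from the naive WT libraries. Of 801 autosomal genes that changed at least 2-fold in naive cells, 86.3% had the same sign in memory cells, whose table lists none of Ddx3y, Eif2s3y, Kdm5d and Uty, which argues against sex makeup as the whole source of the naive genotype effect (in effector cells, 51.0% of 677). Cells of male mice may be present in the naive cKO libraries, since Kdm5c, Kdm6a and Eif2s3x, X-linked genes that escape inactivation, had a median ratio of cKO over WT of 0.765. Both sexes may be present in each of these 3 libraries, since the lowest Xist level was 25.1% of the WT mean. The sex of the animals stays open as a biological difference between the naive groups. Its part in the naive effect, and in the differences of the other subsets from naive cells, was not tested further.

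Markers of other blood cell types were higher in the memory cKO libraries. A lower share of CD8 T cells would raise the markers of every other type alike only if those types gave all marker reads. The lowest myeloid marker ratio of a cKO library was 2.603 times the highest B cell marker ratio. WT memory libraries already held 1122 CPM of B cell markers against 98.0 of myeloid markers. Reads of B cell markers from other sources could hold their ratio down, so the unequal ratios cannot decide. The summed values of Ighm, Cd79a and Cd79b had a ratio of cKO over WT of 0.957. That argues against more B cells only as far as these reads came from B cells. Myeloid markers themselves rose, 89.5% of those measured (17 of 19), among them Mpeg1, Cst3 and Lyz2 at means of 3074, 2564 and 2249 normalised reads in cKO against 271, 709 and 114 in WT. That rise is the pattern itself, so more myeloid and dendritic cells in the cKO cultures, which may be its source, cannot be told apart from expression by the cultured CD8 T cells, and the labels describe no sort or gate.

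Hspa9, the gene targeted by the knockout, had more reads in the libraries labelled cKO. Over TMM, RLE, upper-quartile and library-total scaling, its lowest log2 fold change was 0.69 in naive and 0.45 in memory cells, called under all 4, while they moved the median of all genes by 0.12 and 0.10, which argues against scaling between libraries in these subsets; in effector cells (lowest 0.15) they moved it by 0.0068, too little to decide. A joint rise of mitochondrial chaperone and protease genes was argued against by their median of -0.0733 in naive cells without Hspa9. Exchanged group labels cannot be told apart from a transcript that stays abundant after deletion, since a full exchange would only turn the log2 fold change of 0.69 in naive cells to its negative and no outside reference is at hand. A deleted exon or loss of the protein cannot be seen in gene-level counts, and no other biological explanation was tested.

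Other splits of the same samples were counted for each number of called genes. With 10 splits of 6 libraries there are too few for a share under 0.05. The real values were 3454, 2779 and 2793 genes for naive, effector and memory cells, and 10484, 5804 and 9590 for WT effector against naive, memory against naive and memory against effector cells, and the highest other split gave 0 in each case, so 1 of 10 splits reached each real count. For the interactions, 1 of 100 splits gave as many genes for effector minus naive cells (2902, highest other 1677), a share under 0.05. The same held for memory minus naive cells (2652, highest other 2189). Of these splits, 76 and 77 mixed the genotypes in both subsets, and each of those gave 0 genes. The splits move genotype labels within a subset, so they test for no genotype effect rather than for equal effects. Their shares therefore cannot exclude chance for a difference between subsets in any of the 3 interactions. For memory minus effector cells 4 of 100 splits gave as many genes, also a share under 0.05, with 1367 for the real split and 3318, 1677 and 1498 for the 3 others. These 3 point to a structure of the samples. The split with 3318 genes exchanges WT and cKO in 1 of the subsets only, so that genotype effects of both subsets in the same direction add up, and the splits with 1677 and 1498 keep the genotypes of memory cells while those of effector cells are mixed.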

How the results depend on the processing

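The edgeR test, planned as the main test for counts, was made an alternative on recovered reads after the data were seen. Limma on TMM-scaled values, the fit without genes on chromosomes X and Y, and the TMM factors for summed markers were chosen after seeing the data. The other alternatives were planned. Apart from leaving out libraries, of 138 values of the main results 123 kept their direction and their side of the threshold, or stayed within 1.5 times the count, and 15 changed. For the named genes, with libraries left out included, 12887 of 13260 values were the same, 373 lost the call and 0 reversed.

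An absolute log2 fold change of at least 1, stricter by construction, left 892, 491 and 1079 genes in naive, effector and memory cells. The fit of all 18 libraries called 1519 genes in effector cells; the cause was not tested. Counts for naive, effector and memory cells were 3096, 2147 and 2582 with DESeq2, 3432, 2819 and 2869 with edgeR, 3456, 2769 and 2832 with TMM scaling, and 3356, 2704 and 2749 without chromosomes X and Y. Leaving out chromosomes X and Y keeps any effect of sex on autosomal genes. With a replicate block the counts were 2469, 2687 and 2226, although libraries with the same number did not pair (r of -0.35 to 0.30). With the replicate block and an estimated correlation, camera called 0 lists in naive, effector and memory cells (lowest adjusted p = 0.20, 0.17 and 0.24), against 5, 6 and 6 at an unadjusted p under 0.05, 18, 18 and 17 with the preset correlation and 15, 16 and 12 with fry; the block leaves fewer degrees of freedom by construction.

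Leaving out 1 library at a time, with fewer samples, gave 2127 to 3301 genes in naive, 2082 to 2525 in effector and 1830 to 3049 in memory cells. The count moved over 1.5 times without naive cKO 1 (2138), naive cKO 2 (2127), memory WT 3 (1830) and memory cKO 3 (1836). Interactions gave 2387 to 2823 for effector minus naive, 1934 to 2945 for memory minus naive and 1002 to 1500 for memory minus effector cells. WT comparisons gave 9860 to 10079, 4749 to 5163 and 8847 to 9206 in the order effector against naive, memory against naive, memory against effector.

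Hspa9 was higher in cKO under each alternative run, with log2 fold changes of 0.65 to 0.72 in naive, 0.13 to 0.21 in effector and 0.46 to 0.50 in memory cells when 1 library was left out. In effector cells the call was lost in the fit of all 18 libraries (0.16, adjusted p = 0.099) and without WT 1 (adjusted p = 0.15), WT 3 (0.060), cKO 2 (0.16) or cKO 3 (0.12), over a range of 0.0042 to 0.16 across alternatives. The cause was not tested beyond the smaller number of samples.

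With an estimated correlation, called lists fell from 18 to 4 in naive, 17 to 6 in effector and 19 to 2 in memory cells; from 12 to 5, 18 to 6 and 17 to 8 for effector minus naive, memory minus naive and memory minus effector; and from 21 to 10, 17 to 10 and 15 to 6 for the WT comparisons. With fry, 34 of 36 lists were called for WT memory against effector cells; the cause was not tested. The summed myeloid markers in naive cells had a ratio of cKO over WT of 1.07, and 0.986 with TMM factors. TMM factors scale all genes of a library alike, and multiplied the naive ratio of CD8 T cell identity markers by 0.922. A shift of that size takes the myeloid ratio below 1. Of the other 23 summed marker ratios, 7 moved lower by more than the spread between replicates and kept their side of 1, and 16 stayed within it. Depth and 3 replicates limit small changes, with 37, 41 and 37 of 50 simulated changes of 1.5-fold recovered in naive, effector and memory cells. The simulations changed far fewer genes than were called in the data, and none with few reads, so recovery in the data may differ.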

Other observations

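The tests in this part were chosen only after the results were seen.

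The genotype effects of the 3 subsets share no library. Genes called higher in both memory and naive cells numbered 545 (153 with independent calls), and genes called lower in both numbered 310 (124 with independent calls). Memory and effector cells shared 633 higher (165 with independent calls) and 202 lower genes (90.1 with independent calls), and effector and naive cells 325 higher (156 with independent calls) and 134 lower genes (152 with independent calls), with 205 and 316 genes called in opposite directions. In all 3 subsets, 209 of 12554 genes were called higher and 57 lower, against 14.0 and 11.4 with independent calls. Among them, chosen after their values were seen, were Spry2 (log2 fold changes of 4.21, 2.79 and 2.94 in naive, effector and memory cells), Klra7 (4.38, 3.48 and 3.55), Trgc4 (3.40, 3.58 and 3.83), Slc28a2b (-1.68, -2.06 and -2.78) and Cd8b1 (-0.46, -0.71 and -0.83).

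A strain segment carried along with the targeted allele might place called genes around Hspa9. Within 10 Mb of it, 23 of 102 genes were called in naive cells (odds ratio 0.885, Fisher exact p = 0.73), 7 of 101 in effector cells (odds ratio 0.294, p = 4.0e-04) and 15 of 103 in memory cells (odds ratio 0.720, p = 0.26), against the other autosomal genes. No subset had more calls near Hspa9 than elsewhere, which argues against a segment that raises the calls within 10 Mb of it. The window holds too few genes to be a source of many calls, and segments elsewhere were not tested.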
